A study of Mus musculus with 10 samples.

How the data were processed

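RNA was sequenced from 3 myeloid cell types, defined by surface markers, of C57BL/6 mice 7 days after a metal wire had been placed in the canal of the femur and its tip inoculated with Staphylococcus aureus USA300, a model of implant biofilm infection. Mice of both sexes were used, and EdU was injected before death, per the labels. Per the labels, cells positive for Ly6G and Ly6C were divided by their CD11b level into a CD11b-high population, called myeloid-derived suppressor cells (MDSC, 4 libraries), and a CD11b-low population, called neutrophils (PMN, 3 libraries). Cells positive for Ly6C and negative for Ly6G were called monocytes (MONO, 3 libraries). Libraries were made from total RNA with the low-input version of the ScriptSeq Complete kit and sequenced as paired ends on a NextSeq500 instrument, per the labels. The labels do not say whether each library came from 1 animal or from a pool, so the p-values measure the spread between these libraries, part of which may be technical.

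The deposited gene table holds expected counts, estimated by Salmon 0.8.2 per the submitters' processing notes, for 33473 Ensembl genes in 10 columns, each of which matched 1 library title. The genome build was GRCm38.p5 per the same notes, which also name DESeq2 without a version. The annotation release, the strand setting, the model formula and the way transcripts were summed to genes were not given in the sources used here. The deposited transcript table of each library holds expected counts (NumReads), TPM and effective lengths in bases, per the file headers. Summed transcript counts equalled the gene table within 0.5 counts in every library for 98.3% of genes. The TPM values were deposited by the authors as Salmon wrote them and entered no test. Of the authors' own comparisons, 3 deposited tables were used, which hold a log2 fold change, its standard error, a p-value and an adjusted p-value per gene, per the file headers. The deposited tables with the groups in the reverse order were not used here.

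The expected counts were rounded to whole numbers. Symbols, positions and biotypes came from GENCODE M21, a GRCm38 annotation, matched by Ensembl identifier, which gave a symbol to 33060 of the 33473 genes. Salmon assigns a fragment that fits several transcripts by estimation, so levels of near-identical genes (Ly6c1 and Ly6c2, the Stfa cluster with Gm5483, the globins and the immunoglobulin segments) are uncertain, as are those of overlapping or antisense genes.

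Total counts ranged from 12949567 to 30231332 per library. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr on the groups (18004 genes tested), the quasi-likelihood F test over all 10 libraries with the group as the only term, and Benjamini-Hochberg adjustment at 0.05. A gene is called where its adjusted p was below 0.05. Levels are CPM of the TMM-scaled library size, given as mean ± SD with n = 4 for MDSC and n = 3 for PMN and MONO. Log2 fold changes are fitted by edgeR with their standard errors (SE). For a gene without counts in some libraries, such as Prok2 in MONO, the fitted value depends on the prior count of the fit.

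Before the data were examined, 26 gene lists, the comparisons, the tests and the alternatives were fixed. Each list was set against all other tested genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 26 lists, where it had at least 5 tested members. No list call held with a correlation estimated from the data for each list, and that adjusted p stands beside each call. The rule for named genes was fixed at the same time. It takes Ly6g, Ly6c1, Ly6c2, Itgam, Arg1, Nos2, Il10, S100a8 and S100a9 in every comparison. In each direction it takes the 6 called genes with the largest change among those whose libraries did not overlap and whose mean reached 20 CPM in the higher group, leaving out predicted gene models, pseudogenes, immunoglobulin and T cell receptor segments, mitochondrial genes, Y-linked genes and Xist. From each list it takes up to 4 called members with the largest change and at least 5 CPM in the higher group, and where none was called up to 2 members with the highest mean, with the smallest changes left out first to limit the number named. Of the genes that this rule takes, 2 are not reported here. Genes named from the authors' deposited tables, from DESeq2 or from the stricter filter were chosen after their values were seen.

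The numbers in the library titles are shared between the cell types. All 9 correlations between deviations from the group means of libraries with the same number were above 0.1 (0.583 to 0.935). Those between numbers 1 and 3 were also above it (0.335 to 0.506), so this bar alone does not show pairing. Of the 9 libraries with a partner, 7 lay closest to their own number in both other cell types. The other 2, MONO3 and PMN3, lay closer to MDSC4 (0.685 and 0.740) than to MDSC3 (0.628 and 0.724), so MDSC4 resembled the libraries numbered 3. The pairing comes from these values, since the labels state no shared animal, day or batch. A replicate block, the number as a further term of the edgeR fit, called 0 genes in MDSC against PMN, 8414 in MDSC against MONO and 6757 in PMN against MONO, and its value is printed beside each call that it changes and each count of calls that it moves by over 1.5 times.

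The code was tested on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold. With the spread of the unblocked fit, 14%, 19% and 12% of the 4-fold changes were recovered in MDSC against PMN (15329 genes), MDSC against MONO (15329 genes) and PMN against MONO (15200 genes), and 95%, 91% and 80% of the 16-fold changes. With the spread of the blocked fit 93%, 98% and 93% of the 4-fold changes were recovered (16216, 16216 and 16172 genes), and all of the 16-fold changes. Both simulations held no effect of the number and were fitted without the block, so the blocked fit itself was not simulated. Alternatives tried were DESeq2 size factors and upper-quartile factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, a test against a 1.5-fold change, effective-length offsets (known for 99.0% of tested genes), each library left out in turn, fry in place of camera (fry sets a list against no change, camera against the other tested genes), and genes on several lists left out. After the data were seen, fits without the 3 libraries numbered 2 were added, with and without the block, and list tests with the block and an estimated correlation. Fry was run only without the block.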

Results

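Transcripts were counted in 10 libraries of myeloid cells taken 7 days after infection of a femoral implant with Staphylococcus aureus, which grows on such implants as a biofilm. The libraries comprised 4 of MDSC (Ly6G and Ly6C positive, CD11b high), 3 of PMN (Ly6G and Ly6C positive, CD11b low) and 3 of MONO (Ly6C positive, Ly6G negative), numbered 1 to 4 or 1 to 3. MDSC are myeloid cells known for limiting immune responses, PMN are neutrophils, and the series asks how far the Ly6G and Ly6C positive infiltrate is heterogeneous. Total counts were 23643121, 12949567, 30231332 and 28116795 in MDSC1 to MDSC4, 15437037, 13937693 and 28995436 in PMN1 to PMN3, and 18533771, 16369824 and 29530544 in MONO1 to MONO3. No 2 libraries of a group agreed within sampling noise. The closest pair, MDSC3 and MDSC4, had a chi-square of 9.33 per degree of freedom, against at least 147 in other pairs of a group.

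The libraries numbered 2 stood apart in all 3 cell types. Gm10800, a predicted gene model, and related models took 29.3% of the counts in MDSC2, 25.8% in PMN2 and 14.4% in MONO2, and at most 0.00654% in the other libraries. Between 29531 and 30189 genes had counts in the libraries numbered 2, against 16537 to 18222 in the others. The first principal component (55.7% of the variance) separated these 3 libraries from the rest, and the second (31.1%) separated MONO from MDSC and PMN. Without them the common biological coefficient of variation was 0.411, against 1.05 with them. Counts with and without these libraries are therefore given side by side.

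**Figure D1:**
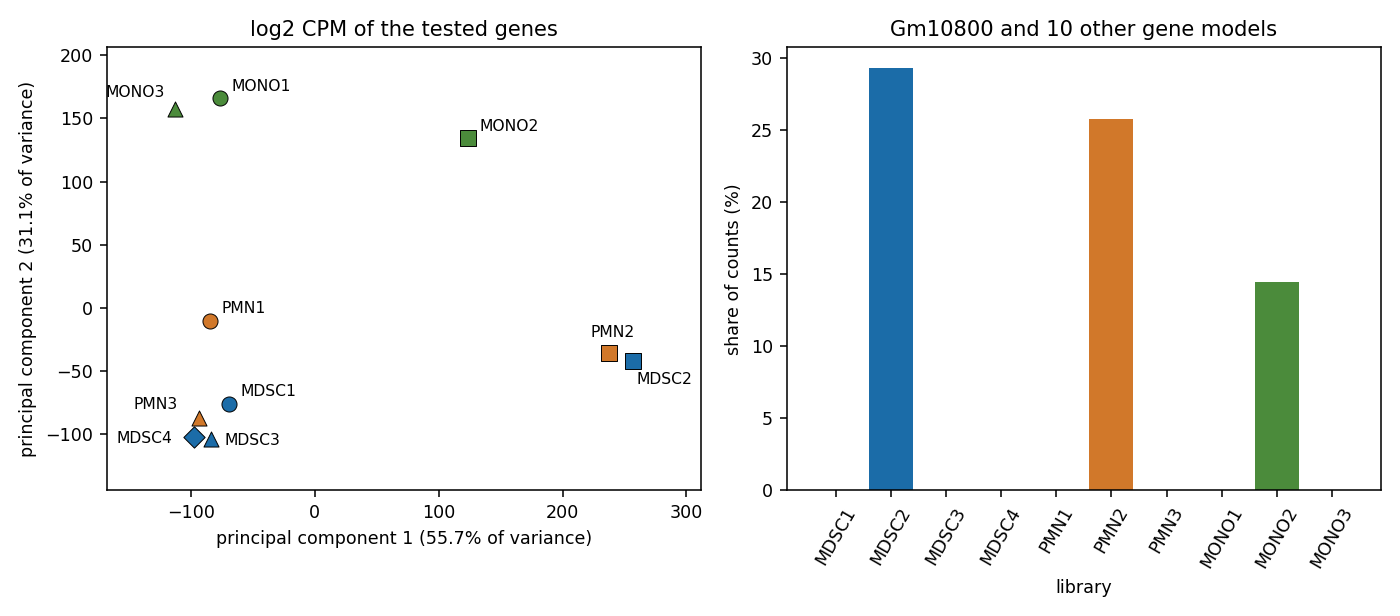
The left panel places the 10 libraries by the first 2 principal components of log2 CPM over the tested genes (55.7% and 31.1% of the variance; circle, square, triangle and diamond for numbers 1, 2, 3 and 4). The right panel gives the share of counts (%) of Gm10800 and related gene models, 29.3%, 25.8% and 14.4% in MDSC2, PMN2 and MONO2 and near 0 elsewhere.

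MDSC and PMN were compared to learn what distinguishes the CD11b-high from the CD11b-low part of the Ly6G and Ly6C positive cells. By camera with its preset correlation, lists of immediate early genes, inflammatory cytokines and chemokines, interferon response genes, suppressive effectors and mature neutrophil genes were called higher in MDSC. None of the 14 list calls held with an estimated correlation (lowest adjusted p = 0.27). No single gene passed the edgeR test, while DESeq2 called 31 and edgeR with the stricter filter on low counts 1. Camera sets a list against the other tested genes, whereas fry asks whether its genes move one way against no change, and fry called 0 lists. Fry was run only without the replicate block, so its 0 lists do not show that no list moved within the numbers. Lists of secondary granule genes, cell division genes and T and NK cell markers were called higher in PMN, also lost with an estimated correlation, and the direction of the secondary granule and the G2 and M phase lists turned without PMN1 (adjusted p = 0.749 for both). Arg1, the arginine-degrading enzyme used as a marker of suppressive myeloid cells, averaged 57.1 ± 5.16 CPM against 14.7 ± 7.30 CPM in PMN and was higher in MDSC in 3 of 3 numbers, with an edgeR log2 fold change of 1.96, SE 0.68, adjusted p = 1. Il1b, which encodes the cytokine interleukin-1 beta, averaged 16527 ± 8276 CPM against 4051 ± 2229 CPM (log2 fold change 2.03, SE 0.90, adjusted p = 1).

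Among the lists that were higher in MDSC, the immediate early and stress genes had a median log2 fold change of 0.99, with 19 of 20 members above 0 (camera adjusted p = 1.4e-20). The call was lost at adjusted p = 0.27 with an estimated correlation, and 4 members passed when adjusted over the list alone. Zfp36, which destabilises cytokine mRNAs, averaged 4683 ± 1670.1 CPM against 1512 ± 290.5 CPM. For pro-inflammatory cytokines and chemokines the median was 1.08, with 25 of 30 members above 0 (camera adjusted p = 1.2e-17, and adjusted p = 0.27 with an estimated correlation), and 1 member was lower when adjusted over the list alone. The chemokine gene Cxcl2 averaged 8030.4 ± 1942 CPM against 2884 ± 1314 CPM. Type I interferon response genes had a median of 0.81 and 31 of 32 members above 0 (camera adjusted p = 7.3e-18, and adjusted p = 0.27 with an estimated correlation). Gbp2, an interferon-induced GTPase gene, averaged 3579 ± 1516 CPM against 1491 ± 775 CPM. MDSC2 had a mean log2 CPM of 6.94 on this list, below the 7.75 to 7.76 of the other MDSC libraries. The suppressive effectors had a median of 0.51 (22 of 27 above 0, camera adjusted p = 1.6e-12, and adjusted p = 0.27 with an estimated correlation). Within this list Nos2 averaged 589 ± 114 CPM against 415 ± 152 CPM. Il10 averaged 4.50 ± 1.53 CPM against 5.64 ± 4.11 CPM, S100a8 10205 ± 3325 CPM against 10893 ± 8736 CPM and S100a9 12688 ± 5384 CPM against 11359 ± 8573 CPM, and these 3 genes differed by less than the SD of either group. PMN1 held 20891 CPM of S100a8, against 4732 and 7055 CPM in PMN2 and PMN3.

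Bacterial sensing and uptake receptors had a median of 0.65 (26 of 31 above 0, camera adjusted p = 1.3e-11, and adjusted p = 0.41 with an estimated correlation). Cd14, a receptor gene for lipopolysaccharide, averaged 13593 ± 7715 CPM against 5129 ± 4567 CPM. PMN3 held 10402 CPM, against 2548 and 2437.5 CPM in PMN1 and PMN2, and lay above MDSC1 (9757 CPM) and MDSC2 (4604 CPM). Mature neutrophil genes had a median of 0.75 (24 of 28 above 0, camera adjusted p = 2.7e-11, and adjusted p = 0.4 with an estimated correlation). Monocyte genes (0.22, camera adjusted p = 0.00022, and adjusted p = 0.43 with an estimated correlation) and macrophage genes (0.22, camera adjusted p = 9.9e-05, and adjusted p = 0.44 with an estimated correlation) moved less. Without PMN2 these last 3 calls were lost (adjusted p = 0.187, 0.302 and 0.0972). Glycolysis genes were called with a median of 0.14 (camera adjusted p = 0.017, and adjusted p = 0.7 with an estimated correlation), but not with the replicate block (adjusted p = 0.569), without the libraries numbered 2 (0.232), without MDSC3 (0.187) or MDSC4 (0.392) or with DESeq2 (0.0585), and the direction turned without PMN2 (0.317). By edgeR no member of any list was called over all genes, whereas DESeq2 called some, among them Egr1, Egr3 and Gzmb.

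The secondary granule genes, which encode the contents of granules made while neutrophils mature, were lower in MDSC, with a median of -1.76 and 4 of 20 members above 0 (camera adjusted p = 6.2e-05, and adjusted p = 0.54 with an estimated correlation). Ngp, a granule protein gene, averaged 939 ± 1469 CPM against 8303 ± 12502 CPM, and its level in PMN1 was 22725 CPM against 545 to 1639 CPM in the other PMN libraries. Its MDSC mean likewise rested on MDSC1, with 3142 CPM against 188 to 225 CPM in the other MDSC libraries. In fits without the block the list's call depended on single libraries. Its direction turned without PMN1 (adjusted p = 0.749) and the call was lost without MDSC2 (0.262). Each of these 2 fits left the same-numbered library of the other group without its partner. The replicate block kept the call, and the list mean was higher in PMN in numbers 1, 2 and 3 (by 2.09, 1.42 and 0.15 on the log2 scale). Primary granule and early neutrophil genes had a median of -1.23 and were not called (adjusted p = 0.11), with 1 member lower when adjusted over the list alone. They were called lower without MDSC1 (0.00365), PMN2 (0.000395) or PMN3 (0.0163) and with DESeq2 (0.000196), and higher without PMN1 (0.0142). The G2 and M phase genes (-1.26, 1 of 32 above 0, camera adjusted p = 4.0e-06, and adjusted p = 0.56 with an estimated correlation) and the S phase genes (-0.41, 5 of 30 above 0, camera adjusted p = 0.0061, and adjusted p = 0.54 with an estimated correlation) were lower in MDSC. Both calls were lost without PMN1, where the direction of the first turned (adjusted p = 0.749 and 0.641).

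Markers of T and NK cells, which the surface markers of neither population select, were lower in MDSC than in PMN, with a median of -1.51 and 2 of 20 members above 0 (camera adjusted p = 6.5e-12, and adjusted p = 0.27 with an estimated correlation). Adjusted over the list alone 7 members were lower. Gzmb, a cytotoxic granule protease gene, averaged 1.12 ± 0.760 CPM against 23.9 ± 31.1 CPM (log2 fold change -4.40, SE 1.01, adjusted p = 1), with 59.6 CPM in PMN1, 2.44 CPM in PMN2 and 9.75 CPM in PMN3. The median difference of the list was -3.09, 0.12 and -1.35 in numbers 1, 2 and 3. B cell and plasma cell markers were also lower (-0.92, camera adjusted p = 0.002, and adjusted p = 0.54 with an estimated correlation), but not without PMN1 (adjusted p = 0.388). Respiratory chain genes were not called (median -0.17, adjusted p = 0.48), and were called lower with the replicate block (adjusted p = 9.73e-06, and adjusted p = 0.58 with an estimated correlation and the block). They were also called lower without the libraries numbered 2 (0.0276), MDSC3 (0.0094), MDSC4 (0.00206) or PMN2 (4.54e-08), and higher without MDSC2 (0.0362) or PMN3 (0.0341).

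**Figure D2:**
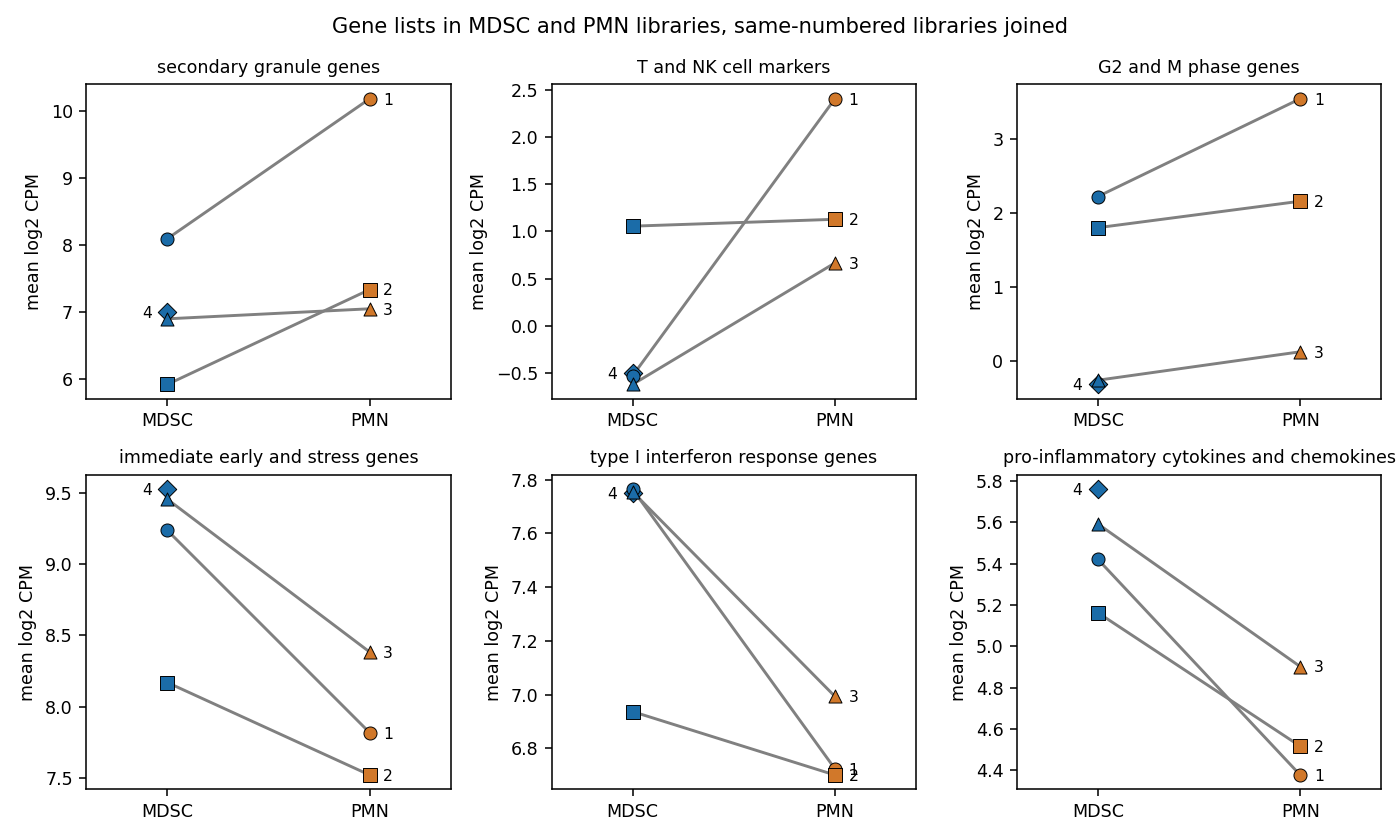
Mean log2 CPM of 6 gene lists in each MDSC and PMN library, with libraries of the same number joined by a line and MDSC4, which has no partner of its number, unjoined (markers by number). Immediate early, interferon and cytokine lists were higher in MDSC in all 3 numbers, and secondary granule, T and NK cell and G2 and M phase lists were higher in PMN, with T and NK cell means of 1.06 in MDSC2 and 1.13 in PMN2.

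Transcripts of the surface markers were not called. Itgam, which encodes CD11b, averaged 866 ± 239 CPM against 919 ± 624 CPM (log2 fold change -0.09, SE 0.58, adjusted p = 1), and was higher in MDSC in 1 of 3 numbers, with 1639 CPM in PMN1 and 579 and 539 CPM in PMN2 and PMN3. Ly6g (ENSMUSG00000022582.4, chromosome 15, 75155240 to 75159126, + strand, GRCm38) averaged 40.3 ± 19.6 CPM against 146 ± 183 CPM (log2 fold change -1.85, SE 0.80, adjusted p = 1), Ly6c2 152 ± 67.3 CPM against 252 ± 312 CPM and its near-identical neighbour Ly6c1 0.904 ± 0.870 CPM against 1.83 ± 1.72 CPM. The higher means in PMN rested on PMN1, with 357 CPM of Ly6g, 612 CPM of Ly6c2 and 3.80 CPM of Ly6c1. PMN2 and PMN3 held 38.2 and 41.2 CPM of Ly6g, 74.5 and 67.7 CPM of Ly6c2 and 1.04 and 0.641 CPM of Ly6c1, near the MDSC means of Ly6g and Ly6c1 and below that of Ly6c2. Within number 2, PMN2 exceeded MDSC2 in Ly6g (38.2 against 12.3 CPM) and Ly6c2 (74.5 against 52.3 CPM), but not in Ly6c1 (1.04 against 2.18 CPM). Within number 3, PMN3 exceeded MDSC3 only in Ly6c1 (0.641 against 0.561 CPM), with 41.2 against 42.4 CPM of Ly6g. Of the remaining list members with the highest means, Srgn, a granule proteoglycan gene, averaged 8441 ± 4092 CPM against 2595 ± 1453 CPM, Lyz2, the lysozyme gene, 2585 ± 1165 CPM against 7035 ± 8601 CPM, and Tgm2, a transglutaminase gene, 1534 ± 638 CPM against 583 ± 243 CPM. The higher mean of Lyz2 in PMN also rested on PMN1 (16955 CPM), since PMN2 and PMN3 held 1664 and 2486 CPM, below the MDSC mean. Against the MDSC library of the same number, PMN2 was higher (865 CPM in MDSC2) and PMN3 lower (2870 CPM in MDSC3). The lists of alternative activation genes (median -0.17, adjusted p = 0.055), MHC class II and dendritic cell genes (0.05, adjusted p = 0.3) and NADPH oxidase genes (0.12, adjusted p = 0.63) were not called. Of these, MHC class II genes were called higher without PMN1 (adjusted p = 0.000163), and NADPH oxidase genes were called higher without PMN1 (0.00838) and lower without PMN2 (0.0458). Alternative activation genes, whose median was below 0, were placed higher in MDSC by camera. They were called without MDSC3 (0.0202), MDSC4 (0.0464), MONO1 (0.0167), MONO2 (0.0098), MONO3 (0.0119) or PMN1 (0.000146). They were also called with limma-voom (0.0104), no filter (0.0169) and the stricter filter (0.00219) on low counts, only the 2 groups compared (0.0313) and upper-quartile factors (0.0496).

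By edgeR 0 of 18004 genes were called between MDSC and PMN, where the lowest adjusted p was 0.441. An unadjusted p under 0.05 was reached by 545 genes, fewer than chance alone would give, and 0 genes were called. The count was also 0 with the replicate block (lowest adjusted p 0.0894, 1754 genes at an unadjusted p under 0.05), without the libraries numbered 2 and with limma-voom. DESeq2 called 31 genes, 21 higher in MDSC and 10 lower, and the stricter filter on low counts called 1, Tagap. The DESeq2 genes higher in MDSC included Egr1, Egr3, Cd69, Cxcl11 and Nfkbid, and those lower in MDSC included the lymphocyte genes Gzma, Gzmb, Gzmc, Ifng, Il2rb, Prf1 and Nkg7. The authors' deposited table had 22 genes past an adjusted p of 0.05 for this comparison, all of them higher in MDSC by the counts and in 3 of 3 numbers. Of these, 12 were among the 31. The 22 were Arg1, Cd69, Csrnp1, Cxcl10, Egr1, Egr2, F3, Gk, Hdc, Homer1, Il18, Isy1, Lmnb1, Nr4a3, Ppp1r16b, Ptgs2, Rab44, Tagap, Tgm1, Thbs1, Tinf2 and Zfp36l1, with edgeR log2 fold changes from 1.47 to 2.71 here. Among them Tagap (ENSMUSG00000033450.7, chromosome 17, 7926000 to 7934897, + strand, GRCm38), a gene of activated immune cells, averaged 308 ± 89.7 CPM against 53.4 ± 5.64 CPM (log2 fold change 2.53, SE 0.37, adjusted p = 0.44). The median log2 fold change of all tested genes was -0.15 with TMM, -0.07 with DESeq2 size factors and -0.03 with upper-quartile factors. It was 0.393 without PMN2 and below 0 in all other settings. The list medians of 0.14 to 0.22 come from the fit with PMN2, so they cannot be set against that 0.393.

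MDSC and MONO were compared to set the CD11b-high cells against the Ly6G-negative monocytes of the same infection. Genes called higher in MDSC included 25 of 28 mature neutrophil genes, 14 of 30 pro-inflammatory cytokines and chemokines (5 lower), 20 of 32 interferon response genes (1 lower) and 11 of 27 suppressive effectors. Genes called higher in MONO included 14 of 24 monocyte genes (1 lower), 11 of 24 MHC class II and dendritic cell genes (2 lower) and 10 of 17 primary granule genes (1 lower). They also included 15 of 30 S phase, 19 of 32 G2 and M phase and 16 of 38 respiratory chain genes. Camera called 15 lists, none of which held with an estimated correlation (adjusted p = 0.35 to 0.68). Against no change, which is another question than that of camera, fry called 13 of the same lists, and gave adjusted p = 0.233 for the secondary granule and 0.0695 for the respiratory chain list. Asprv1 (ENSMUSG00000033508.7, chromosome 6, 86628164 to 86629710, + strand, GRCm38), a protease gene, averaged 958 ± 473 CPM against 1.63 ± 1.43 CPM (log2 fold change 9.19, SE 1.12, adjusted p = 0.00073). Mmp9 (ENSMUSG00000017737.2, chromosome 2, 164940780 to 164955850, + strand), which encodes a gelatinase stored in neutrophil granules, averaged 1808 ± 945 CPM against 6.03 ± 3.27 CPM (log2 fold change 8.23, SE 1.19, adjusted p = 0.0014). Ccr2 (ENSMUSG00000049103.14, chromosome 9, 124101950 to 124113557, + strand), the chemokine receptor gene that marks inflammatory monocytes, averaged 13.8 ± 10.003 CPM against 1169.5 ± 402 CPM (log2 fold change -6.41, SE 0.84, adjusted p = 0.00093).

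Of 28 mature neutrophil genes 25 were higher in MDSC and none lower (26 when adjusted over the list alone), with a median of 4.53 against 0.53 over all tested genes (camera adjusted p = 3.9e-21, and adjusted p = 0.35 with an estimated correlation). Stfa2l1, a stefin gene with close copies nearby, averaged 163 ± 57.99 CPM against 0.646 ± 0.537 CPM. MDSC2 lay below the other MDSC libraries here, with a mean log2 CPM of 8.24 against 9.35 to 9.86. Secondary granule genes were called as a list (median 1.23, camera adjusted p = 0.019, and adjusted p = 0.68 with an estimated correlation), with 6 of 20 higher and none lower (7 and 2 with the block), among them Olfm4 (50.2 ± 19.1 CPM against 0.626 ± 0.608 CPM) and Ly6g (40.3 ± 19.6 CPM against 0.584 ± 0.286 CPM, log2 fold change 6.10, SE 1.05, adjusted p = 0.0029). This list call was lost with the replicate block (adjusted p = 0.115), without MDSC1 (0.129) and without MONO2 (0.123). S100a8 (10205 ± 3325 CPM against 718 ± 337 CPM, log2 fold change 3.83, SE 0.83, adjusted p = 0.0083) and S100a9 (12688 ± 5384 CPM against 548 ± 258 CPM, log2 fold change 4.53, SE 0.90, adjusted p = 0.0055), the subunits of calprotectin, were higher in MDSC. Primary granule and early neutrophil genes went the other way, with 1 of 17 higher and 10 lower (1 and 12 when adjusted over the list alone). Their median was -3.64 (camera adjusted p = 2.3e-05, and adjusted p = 0.38 with an estimated correlation). Mpo, the myeloperoxidase gene (ENSMUSG00000009350.13, chromosome 11, 87793581 to 87804413, + strand), averaged 3.54 ± 4.13 CPM against 719 ± 347 CPM (log2 fold change -7.66, SE 1.69, adjusted p = 0.0091). The protease gene Ctsg averaged 0.314 ± 0.289 CPM against 55.2 ± 23.8 CPM, and Nkg7, which is also known from cytotoxic lymphocytes, 1.03 ± 0.520 CPM against 196 ± 80.8 CPM.

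The suppressive effectors had 11 of 27 members higher and none lower (11 and 1 when adjusted over the list alone, and 21 and 0 with the block), with a median of 1.84 (camera adjusted p = 3.1e-08, and adjusted p = 0.38 with an estimated correlation). Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095, + strand), which encodes the checkpoint ligand PD-L1, averaged 3503 ± 362 CPM against 105 ± 49.1 CPM (log2 fold change 5.06, SE 0.63, adjusted p = 0.00077). Il10 was low in both (4.50 ± 1.53 CPM against 0.639 ± 0.360 CPM, log2 fold change 2.80, SE 0.76, adjusted p = 0.023), and its call was lost without MDSC3 (adjusted p = 0.0507), MDSC4 (0.0605), MONO1 (0.229) or MONO3 (0.093) and with no filter on low counts (0.141). Arg1 averaged 57.1 ± 5.16 CPM against 197 ± 160.01 CPM, with 34.2 CPM in MONO2 and 203 and 354 CPM in MONO1 and MONO3, and was not called (log2 fold change -1.79, SE 0.64, adjusted p = 0.072). It was called lower in MDSC without the libraries numbered 2 (adjusted p = 0.00501), without MONO2 (0.00775) and without PMN1 (0.0324), and also with DESeq2 (0.0483), no filter on low counts (0.016) and the stricter filter (0.0465). Nos2 averaged 589 ± 114 CPM against 301 ± 291 CPM and Itgam 866 ± 239 CPM against 467 ± 271 CPM, both not called.

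Pro-inflammatory cytokines and chemokines had 14 of 30 members higher and 5 lower (15 and 5 when adjusted over the list alone). Their median was 1.79 (camera adjusted p = 3.7e-05, and adjusted p = 0.39 with an estimated correlation). Il23a, a subunit of interleukin-23, averaged 28.96 ± 9.62 CPM against 0.287 ± 0.217 CPM, and the chemokine gene Ccl3 3409.8 ± 1326 CPM against 45.3 ± 16.2 CPM, whereas Ifng averaged 0.101 ± 0.0754 CPM against 26.8 ± 19.3 CPM. Type I interferon response genes had 20 of 32 higher and 1 lower (24 and 2 when adjusted over the list alone, 25 and 3 with the block). Their median was 1.99 (camera adjusted p = 9.8e-09, and adjusted p = 0.38 with an estimated correlation). The antiviral gene Rsad2 averaged 1959.7 ± 622 CPM against 40.6 ± 20.1 CPM. Bacterial sensing and uptake receptors had 15 of 31 higher and 5 lower (17 and 6 when adjusted over the list alone). Their median was 2.15 (camera adjusted p = 0.00012, and adjusted p = 0.65 with an estimated correlation). The formyl peptide receptor gene Fpr1 averaged 844 ± 308 CPM against 17.8 ± 16.7 CPM. Immediate early and stress genes had 12 of 20 higher and 1 lower (16 and 1 when adjusted over the list alone). Their median was 2.25 (camera adjusted p = 9.2e-08, and adjusted p = 0.38 with an estimated correlation). Egr3 averaged 29.6 ± 16.7 CPM against 0.984 ± 0.536 CPM. Glycolysis genes had 9 of 24 higher and 1 lower (16 and 1 when adjusted over the list alone, 20 and 1 with the block). Their median was 1.94 (camera adjusted p = 3.2e-06, and adjusted p = 0.44 with an estimated correlation). The glucose transporter gene Slc2a3 averaged 1016 ± 299 CPM against 23.3 ± 13.9 CPM. Respiratory chain genes were lower, 16 of 38 with none higher (23 when adjusted over the list alone, 33 with the block). Their median was -1.44 (camera adjusted p = 4.7e-06, and adjusted p = 0.67 with an estimated correlation). Ndufa9, a complex I subunit gene, averaged 5.49 ± 1.49 CPM against 71.6 ± 36.3 CPM. The share of counts on mitochondrial genes was 0.729% to 1.24% in MONO and at most 0.145% in the other libraries.

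Monocyte genes were lower in MDSC, with 1 of 24 higher and 14 lower (2 and 18 when adjusted over the list alone, 4 and 19 with the block). Their median was -2.54 (camera adjusted p = 8.6e-06, and adjusted p = 0.38 with an estimated correlation). MHC class II and dendritic cell genes were also lower, with 2 of 24 higher and 11 lower (2 and 14 when adjusted over the list alone). Their median was -1.91 (camera adjusted p = 0.00056, and adjusted p = 0.35 with an estimated correlation). H2-DMa and H2-DMb1, which load peptides onto MHC class II, averaged 4.63 ± 0.723 CPM against 198 ± 157 CPM and 4.71 ± 0.840 CPM against 182 ± 125 CPM. Ly6c2 averaged 152 ± 67.3 CPM against 960.4 ± 281 CPM (log2 fold change -2.66, SE 0.79, adjusted p = 0.036). This call was lost without MDSC1 (adjusted p = 0.0724), MDSC3 (0.0825), MDSC4 (0.0756), MONO1 (0.0531) or MONO3 (0.0963) and in the test against a 1.5-fold change (0.0545). Ly6c1 averaged 0.904 ± 0.870 CPM against 4.80 ± 1.65 CPM (adjusted p = 0.081, called with the block at 0.0424, without the libraries numbered 2 at 0.0106, without MDSC2 at 0.0118 and without PMN1 at 0.0366). It was also called with DESeq2 (0.0265), limma-voom (0.0201) and no filter on low counts (0.0447). Macrophage genes went both ways, 5 of 27 higher and 9 lower (9 and 10 with the block), and were not called as a list (median -1.36, adjusted p = 0.72). Alternative activation genes (-1.69, adjusted p = 0.31), with Clec10a, a lectin gene, at 0.501 ± 0.274 CPM against 15.9 ± 3.28 CPM, and NADPH oxidase genes (0.85, adjusted p = 0.11) were not called, the latter becoming called without MDSC2 (0.0242) or MONO3 (0.0175) and with genes on several lists left out (0.0375).

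Cell division genes were lower in MDSC. S phase genes had 15 of 30 lower and none higher (17 when adjusted over the list alone). Their median was -2.10 (camera adjusted p = 7.1e-07, and adjusted p = 0.38 with an estimated correlation). G2 and M phase genes had 19 of 32 lower (26 when adjusted over the list alone, 30 with the block). Their median was -3.29 (camera adjusted p = 1.2e-08, and adjusted p = 0.46 with an estimated correlation). Mcm3, a subunit of the replicative helicase, averaged 1.20 ± 0.811 CPM against 58.9 ± 28.998 CPM, and the mitotic kinase gene Aurkb 1.13 ± 1.31 CPM against 31.6 ± 22.4 CPM. Mean log2 CPM of the G2 and M phase genes was 3.30 to 5.33 in MONO, 1.80 and 2.23 in MDSC2 and MDSC1, and -0.32 and -0.26 in MDSC4 and MDSC3. T and NK cell markers were lower in MDSC, 15 of 20 with none higher (19 when adjusted over the list alone). Their median was -5.28 (camera adjusted p = 3.8e-12, and adjusted p = 0.35 with an estimated correlation). Gzmb averaged 1.12 ± 0.760 CPM against 159 ± 116 CPM and Trac, the T cell receptor alpha constant gene, 0.413 ± 0.0698 CPM against 46.7 ± 18.6 CPM. Mean log2 CPM of this list was 3.90, 5.55 and 4.62 in MONO1, MONO2 and MONO3 and 1.06 in MDSC2, against -0.62 to -0.50 in the other MDSC libraries. These markers of cells outside the intended population were thus higher in MONO, as were the monocyte, primary granule and cell division lists.

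**Figure D3:**
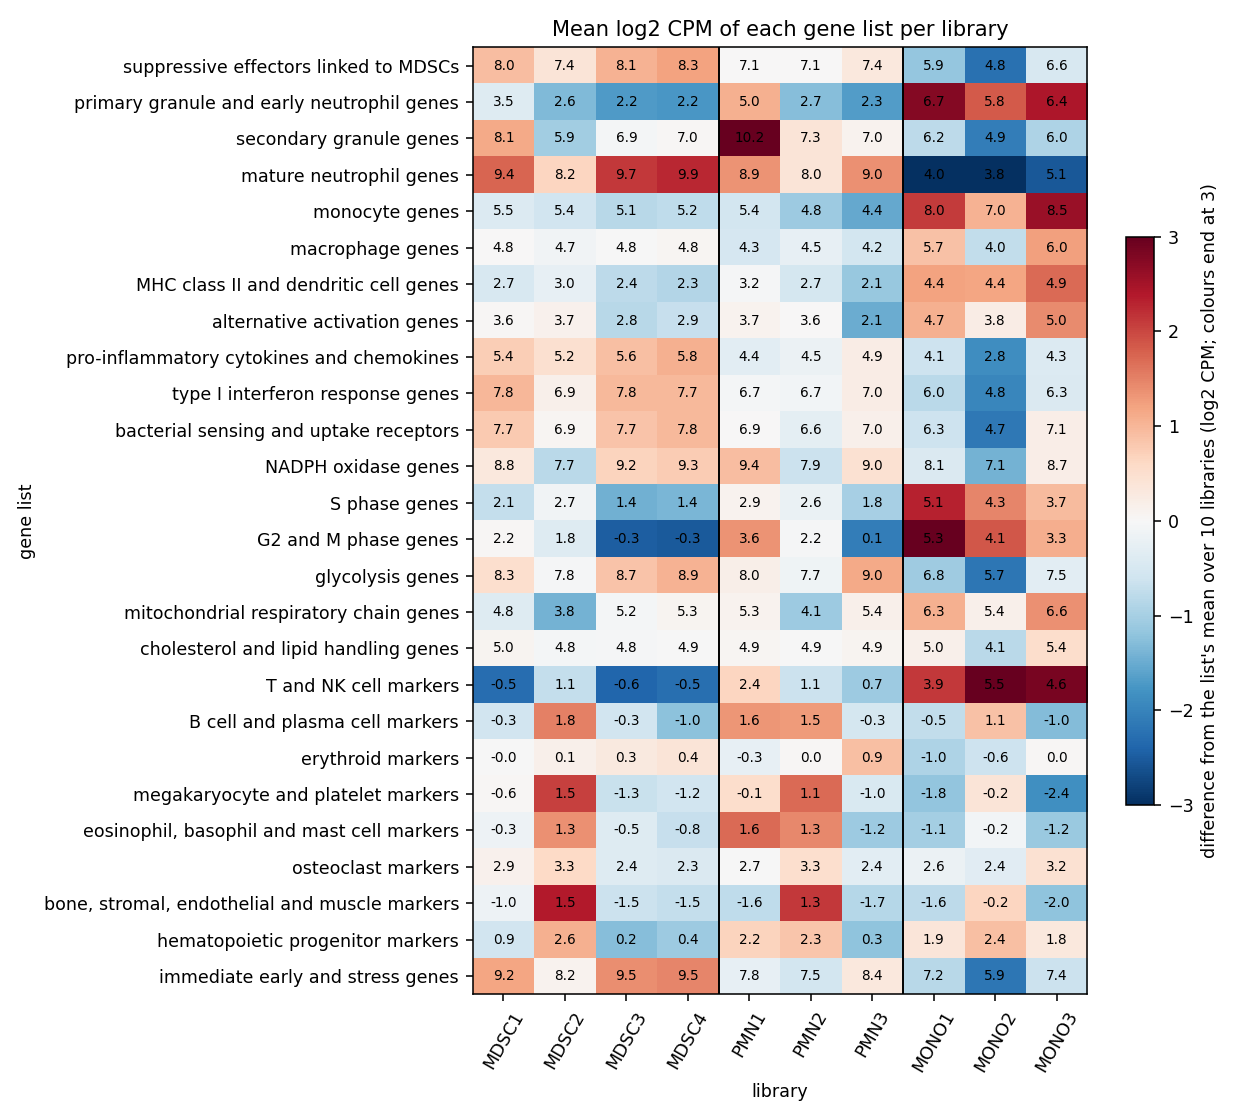
Mean log2 CPM of the 26 gene lists (rows) in each library (columns), printed in each cell and coloured by the difference from the list's mean over the 10 libraries. Mature neutrophil genes lay between 7.99 and 9.86 in MDSC and PMN and between 3.83 and 5.06 in MONO, and T and NK cell markers between 3.90 and 5.55 in MONO.

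By edgeR 1581 genes were higher and 2229 lower in MDSC than in MONO, 3810 of 18004. With upper-quartile factors the split was 2354 and 1945, with no filter on low counts 998 and 2900, without MONO1 711 and 2005 and without MONO3 1247 and 1297. The median log2 fold change of all tested genes was 0.53 with TMM, 0.70 with DESeq2 size factors and 0.73 with upper-quartile factors. Its sign rested on single libraries and on the filter, since it was -0.416 without MDSC2, -0.099 without MONO1, -0.158 without the libraries numbered 2 (-0.157 with the block) and -0.080 with the stricter filter. The replicate block called 4192 higher and 4222 lower, among them 3808 of the 3810, and without the libraries numbered 2 the counts were 3216 and 4259. The 6 genes by rule with the largest increases in MDSC were Asprv1, Mrgpra2a, Prok2, Rufy4, Mmp9 and G0s2, with log2 fold changes from 8.14 to 9.19. Mrgpra2a, a Mas-related receptor gene, averaged 179.6 ± 71.3 CPM against 0.316 ± 0.368 CPM. Prok2, which encodes a chemokine-like peptide, averaged 30.8 ± 10.3 CPM against 0.0510 ± 0.0884 CPM, and Rufy4 28.9 ± 14.2 CPM against 0.0872 ± 0.124 CPM. G0s2, a lipase inhibitor gene, averaged 1585 ± 939 CPM against 5.62 ± 1.01 CPM. Prok2 had no counts in MONO1 and MONO3 and 0.153 CPM in MONO2. Those with the largest decreases were Ifng, Cd7, Il2rb, Mpo, Ctsw and Nkg7, with log2 fold changes from -8.06 to -7.56. Of these, Cd7 (0.243 ± 0.237 CPM against 53.1 ± 22.6 CPM), Il2rb (0.808 ± 0.276 CPM against 175 ± 70.4 CPM) and Ctsw (0.398 ± 0.220 CPM against 78.8 ± 45.99 CPM) are known from lymphocytes.

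PMN and MONO were compared to give the same contrast for the CD11b-low cells. Genes called higher in PMN included 23 of 28 mature neutrophil genes, 7 of 20 secondary granule genes and 4 of 24 glycolysis genes (1 lower). Genes called higher in MONO included 13 of 24 monocyte genes, 8 of 24 MHC class II and dendritic cell genes (2 lower), 7 of 17 primary granule, 8 of 30 S phase and 7 of 38 respiratory chain genes. Camera called 16 lists, none of which held with an estimated correlation (adjusted p = 0.28 to 0.67). Of these, fry called 6 against no change, the mature neutrophil, monocyte, MHC class II, primary granule, S phase and T and NK cell lists. Mmp9 averaged 3042 ± 3115 CPM against 6.03 ± 3.27 CPM (log2 fold change 8.98, SE 1.24, adjusted p = 0.0025; 6610 CPM in PMN1, 860 and 1657 CPM in PMN2 and PMN3) and Ms4a4a (ENSMUSG00000101389.1, chromosome 19, 11375523 to 11392790, + strand, GRCm38), a membrane protein gene of monocytes and macrophages, 1.04 ± 0.663 CPM against 286 ± 214 CPM (log2 fold change -8.11, SE 0.89, adjusted p = 0.0015). Ly6g averaged 146 ± 183 CPM against 0.584 ± 0.286 CPM (log2 fold change 7.95, SE 1.16, adjusted p = 0.003), with 357 CPM in PMN1 and 38.2 and 41.2 CPM in PMN2 and PMN3.

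Mature neutrophil genes had 23 of 28 members higher in PMN and none lower (25 when adjusted over the list alone), with a median of 4.21 against 0.60 over all tested genes (camera adjusted p = 7.0e-21, and adjusted p = 0.28 with an estimated correlation). Secondary granule genes had 7 of 20 higher (10 when adjusted over the list alone, 11 with the block). Their median was 3.12 (camera adjusted p = 3.3e-05, and adjusted p = 0.58 with an estimated correlation). The granule genes Ceacam10 and Olfm4 averaged 70.1 ± 90.2 CPM against 0.469 ± 0.247 CPM and 67.1 ± 45.6 CPM against 0.626 ± 0.608 CPM. The mean of Ceacam10 rested on PMN1 (174 CPM), with 17.6 and 18.3 CPM in PMN2 and PMN3. PMN1 had the highest mean on the secondary granule list, 10.2 log2 CPM against 7.33 and 7.05 in PMN2 and PMN3. S100a8 (10893 ± 8736 CPM against 718 ± 337 CPM, log2 fold change 3.92, SE 0.85, adjusted p = 0.016) and S100a9 (11359 ± 8573 CPM against 548 ± 258 CPM, log2 fold change 4.37, SE 0.91, adjusted p = 0.013) were higher in PMN. These 2 calls were lost without MONO1 (adjusted p = 0.0765 and 0.0692) or MONO3 (0.0659 and 0.0561), and that of S100a8 also without PMN1 (0.062). Primary granule and early neutrophil genes had 7 of 17 lower and none higher (9 lower when adjusted over the list alone, 12 lower and 2 higher with the block). Their median was -3.36 (camera adjusted p = 2.7e-05, and adjusted p = 0.51 with an estimated correlation). Elane, the neutrophil elastase gene, averaged 3.04 ± 3.73 CPM against 228 ± 130.00 CPM (log2 fold change -6.23, SE 1.60, adjusted p = 0.031). Its call was lost without MONO1 (0.0558), MONO3 (0.061), PMN2 (0.0767) or PMN3 (0.104). Prtn3, another serine protease gene, averaged 1.89 ± 2.69 CPM against 102 ± 61.4 CPM (log2 fold change -5.76, SE 1.12, adjusted p = 0.01). Both genes were highest among the PMN in PMN1, at 7.33 and 4.998 CPM, against at most 1.18 and 0.348 CPM in PMN2 and PMN3.

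Suppressive effectors had 7 of 27 members higher and 1 lower (9 and 1 when adjusted over the list alone, 14 and 2 with the block). Their median was 1.31 (camera adjusted p = 0.00011, and adjusted p = 0.58 with an estimated correlation). Cd274 averaged 2511 ± 866 CPM against 105 ± 49.1 CPM (log2 fold change 4.58, SE 0.63, adjusted p = 0.0024), and the lower member was Arg1 (ENSMUSG00000019987.9, chromosome 10, 24915221 to 24927484, - strand) at 14.7 ± 7.30 CPM against 197 ± 160.01 CPM (log2 fold change -3.74, SE 0.76, adjusted p = 0.012). Il10 averaged 5.64 ± 4.11 CPM against 0.639 ± 0.360 CPM (log2 fold change 3.13, SE 0.79, adjusted p = 0.029), and the call was lost without MONO1 (0.243), MONO3 (0.111), PMN2 (0.0535) or PMN3 (0.125), with no filter on low counts (0.141) and with only the 2 groups compared (0.0727). Nos2 (415 ± 152 CPM against 301 ± 291 CPM), Itgam (919 ± 624 CPM against 467 ± 271 CPM), Ly6c1 (1.83 ± 1.72 CPM against 4.80 ± 1.65 CPM) and Ly6c2 (252 ± 312 CPM against 960.4 ± 281 CPM, log2 fold change -1.93, SE 0.86, adjusted p = 0.19) were not called. Ly6c2 was called lower in PMN with the block (adjusted p = 0.00876) and without PMN1 (0.00737). Interferon response genes had 8 of 32 higher and 1 lower (16 and 2 when adjusted over the list alone, 21 and 2 with the block). Their median was 1.11 (camera adjusted p = 3.9e-05, and adjusted p = 0.58 with an estimated correlation). Rsad2 averaged 1127 ± 518 CPM against 40.6 ± 20.1 CPM. Pro-inflammatory cytokines and chemokines had 11 of 30 higher and 5 lower (12 and 7 when adjusted over the list alone). Their median was 0.99 (camera adjusted p = 0.032, and adjusted p = 0.66 with an estimated correlation). Il23a averaged 18.6 ± 18.01 CPM against 0.287 ± 0.217 CPM and Ccl3 1614 ± 1125 CPM against 45.3 ± 16.2 CPM. Both genes were highest among the PMN in PMN3 (39.3 and 2903 CPM), against at most 9.82 and 1102 CPM in PMN1 and PMN2. That list call was lost with the replicate block (adjusted p = 0.146), without the libraries numbered 2 (0.289), without MONO2 (0.538), without PMN3 (0.0851) and with effective-length offsets (0.0556). Bacterial sensing and uptake receptors (10 of 31 higher, 4 lower; 12 and 5 when adjusted over the list alone; 18 and 7 with the block; median 1.12, camera adjusted p = 0.014, and adjusted p = 0.67 with an estimated correlation) lost their call without MONO2 (0.439), PMN1 (0.0554) or PMN3 (0.0939) and with DESeq2 (0.0661). Immediate early and stress genes (3 of 20 higher, none lower, also when adjusted over the list alone; 11 and 1 with the block; median 0.97, camera adjusted p = 0.0041, and adjusted p = 0.65 with an estimated correlation) lost theirs without MONO2 (0.197) or PMN3 (0.0674).

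Monocyte genes had 13 of 24 lower and none higher (14 lower when adjusted over the list alone, 16 lower and 3 higher with the block). Their median was -2.78 (camera adjusted p = 9.8e-09, and adjusted p = 0.28 with an estimated correlation). Ms4a4c averaged 3.61 ± 2.67 CPM against 387 ± 253 CPM and F13a1 (ENSMUSG00000039109.16, chromosome 13, 36867178 to 37050244, - strand), which encodes the A subunit of coagulation factor XIII, 15.8 ± 5.67 CPM against 1222 ± 541 CPM. MHC class II and dendritic cell genes had 8 of 24 lower and 2 higher (9 and 2 when adjusted over the list alone, 14 and 2 with the block). Their median was -2.12 (camera adjusted p = 4.7e-05, and adjusted p = 0.28 with an estimated correlation). H2-DMb1 averaged 4.46 ± 4.75 CPM against 182 ± 125 CPM. Macrophage genes (-1.20, adjusted p = 0.16) had 4 of 27 higher and 9 lower (9 and 11 with the block). They were called lower without the libraries numbered 2 (0.0448), without MONO2 (0.00248) and with no filter on low counts (0.0128). The high-affinity Fc receptor gene Fcgr1 averaged 4.26 ± 1.64 CPM against 171 ± 153 CPM. Alternative activation genes (-1.36, adjusted p = 0.076), led by the scavenger receptor gene Msr1 at 6.43 ± 4.13 CPM against 267 ± 190.01 CPM, were called lower without MONO2 (0.0108) or PMN1 (0.0241) and with no filter on low counts (0.00568). NADPH oxidase genes (0.79, adjusted p = 0.11) were called higher without MONO3 (0.0138), PMN2 (0.0034) or all libraries numbered 2 (0.0441). Glycolysis genes had 4 of 24 higher and 1 lower (the same counts when adjusted over the list alone, 21 and 1 with the block). Their median was 1.76 (camera adjusted p = 9.7e-06, and adjusted p = 0.58 with an estimated correlation). Slc2a3 averaged 786 ± 469.8 CPM against 23.3 ± 13.9 CPM. Respiratory chain genes had 7 of 38 lower and none higher (9 when adjusted over the list alone, 29 with the block). Their median was -1.22 (camera adjusted p = 9.3e-07, and adjusted p = 0.6 with an estimated correlation). S phase genes had 8 of 30 lower and none higher (15 when adjusted over the list alone, 21 with the block). Their median was -1.69 (camera adjusted p = 9.3e-07, and adjusted p = 0.34 with an estimated correlation). G2 and M phase genes were called as a list (median -1.97, camera adjusted p = 9.3e-07, and adjusted p = 0.58 with an estimated correlation) although none of 32 members was called, and 29 were called lower with the block. T and NK cell markers had 10 of 20 lower and none higher (13 when adjusted over the list alone, 17 with the block). Their median was -2.92 (camera adjusted p = 1.6e-10, and adjusted p = 0.34 with an estimated correlation). Cd8b1, a subunit of the CD8 receptor, averaged 0.692 ± 0.788 CPM against 31.95 ± 29.9 CPM (log2 fold change -5.54, SE 1.31, adjusted p = 0.022). That call was lost without MONO2 (0.0688), PMN1 (0.05002) or PMN3 (0.0871).

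**Figure D4:**
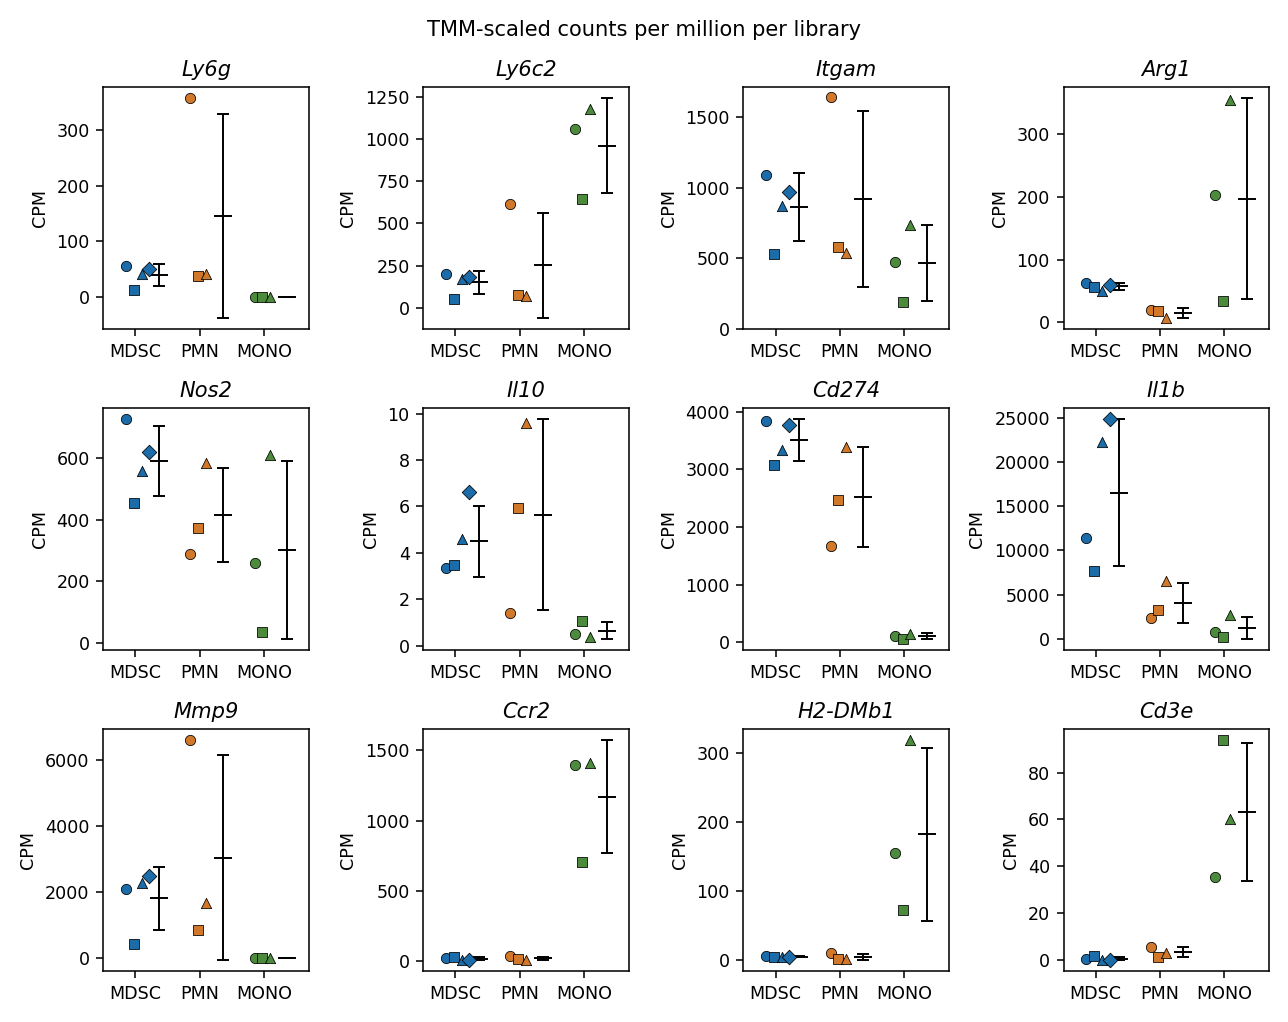
TMM-scaled CPM of 12 genes in each library (circle, square, triangle and diamond for numbers 1, 2, 3 and 4), with the mean ± SD of each group beside the points. Cd274 averaged 3503 CPM in MDSC, 2511 CPM in PMN and 105 CPM in MONO, and Arg1 was higher in each MDSC library than in each PMN library.

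By edgeR 1013 genes were higher and 1061 lower in PMN than in MONO, 2074 of 18004. The split was 1136 and 956 with DESeq2 size factors, 1583 and 1136 with upper-quartile factors, 555 and 1542 with no filter on low counts and 1239 and 1677 with limma-voom, so which direction had more calls depended on the setting. The replicate block called 3553 higher and 3204 lower, among them all 2074, and without the libraries numbered 2 the counts were 2144 and 2478. The count fell to 1188 without MONO1 (313 higher, 875 lower), 1010 without MONO3 (606 and 404) and 995 without PMN3 (545 and 450). The split was 673 and 980 without MONO2, 579 and 1426 without PMN1 and 858 and 602 without PMN2. Without MDSC2, which is in neither group, 3367 of 14438 tested genes were called (1642 and 1725). The genes by rule with the largest increases in PMN were Mmp9, Prok2, Retnlg, Asprv1, Gpr27 and Ly6g, with log2 fold changes from 7.95 to 8.98. Those with the largest decreases included Ms4a4a, Ms4a4c, Pld4, Aldh1b1 and Ly86, with log2 fold changes from -8.11 to -6.46. Asprv1 averaged 572 ± 417 CPM against 1.63 ± 1.43 CPM, Prok2 26.7 ± 9.74 CPM against 0.0510 ± 0.0884 CPM, and Retnlg, a resistin-like gene, 1806 ± 2229 CPM against 4.37 ± 2.53 CPM, with 4380 CPM in PMN1 and 514 and 524 CPM in PMN2 and PMN3. Pld4, Aldh1b1 and Ly86 averaged 552, 20.5 and 158 CPM in MONO against 5.4, 0.22 and 1.81 CPM in PMN. Gpr27, an orphan receptor gene, averaged 20.04 ± 29.96 CPM against 0.0510 ± 0.0884 CPM, with 54.6 CPM in PMN1, 4.53 in PMN2 and 1.01 in PMN3. It lost its call without MONO1 (adjusted p = 0.0791), MONO3 (0.0612) or PMN1 (0.121) and with limma-voom (0.128). The median log2 fold change of all tested genes was 0.60 with TMM, 0.69 with DESeq2 size factors and 0.70 with upper-quartile factors. Its sign turned without PMN2 (-0.737), without the libraries numbered 2 (-0.038, and -0.072 with the block) and with only the 2 groups compared (-0.024). It kept its sign but fell to 0.024 without MONO1 and to 0.029 with the stricter filter.

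Genes that set MDSC apart from both other cell types would need to pass both tests in the same direction. With edgeR 0 genes were higher and 0 lower in MDSC than in both PMN and MONO, with and without the replicate block. The MDSC against PMN test set the limit. Without the block it had 545 genes at an unadjusted p under 0.05, fewer than chance alone would give. With the block 1754 genes reached it, and 1513 of 14049 without the libraries numbered 2, so the shortfall depended on the fit. DESeq2 gave 20 higher and 10 lower, and the stricter filter 1 higher, Tagap, which averaged 308 ± 89.7 CPM in MDSC. The 10 lower were all those that DESeq2 called lower in MDSC than in PMN. They include the lymphocyte genes Gzma, Gzmb, Gzmc, Ifng, Il2rb, Prf1 and Nkg7 and the T cell receptor gene Trbc2. T and NK cell markers were higher in the PMN and MONO libraries, so these genes need not be a trait of MDSC.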

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

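The tests of T and NK cells in PMN, of shares of the MONO level, of swapped labels and of the sign of the deposited fold changes were chosen after the result was seen, as were the fits without the libraries numbered 2. Of 178 values compared among the 4 MDSC libraries, 26 had a library whose gap to the nearest other, divided by the range of the group, was above Dixon's 95% critical value for 4 samples, where chance gives about 1 in 20. Of these, 21 were in MDSC2, 2 in MDSC1, 2 in MDSC3 and 1 in MDSC4. In MDSC2 the gap was 0.935 of the range for the number of genes with counts, 0.99995 for the share of Gm10800 and related models and 0.99998 for that of Gm10800 alone (19.9%). It was 0.981 for interferon response genes and 0.928 for T and NK cell markers. Among single genes of MDSC2 it was 0.889 for Ly6c2, 0.892 for Lyz2, 0.957 for Cd74, 0.876 for Ighm, 0.849 for Siglecf, 0.905 for Il5ra, 0.939 for Egr2, 0.870 for Rufy4, 0.903 for Mmp9, 0.866 for Ctsw, 0.925 for Ifit1, 0.847 for Ncf1, 0.932 for Retnlg, 0.911 for Ctsc, 0.890 for Ceacam10 and 0.888 for Ly6a. In the other libraries it was 0.937 for Ngp and 0.877 for Egr3 (MDSC1), 0.847 for Mcm3 and 0.864 for Clec10a (MDSC3) and 0.987 for Cenpa (MDSC4).

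The libraries numbered 2 stood apart in all 3 cell types. There were 11244 genes at 0 in the other 7 libraries and with counts in at least 1 library numbered 2. Among them the count rose with the length of the longest transcript. The Spearman rho across genes was 0.579 in MDSC2, 0.519 in MONO2 and 0.584 in PMN2. In the libraries numbered 1 and 3, over 90 and 68 such genes, it was 0.0386 to 0.283. Genomic DNA in these libraries may therefore be a source, although a low amount of RNA would also give a relation with length, and genes are not independent replicates. RNA of another cell type cannot be told apart from this. Of those genes 73.7% to 79.1% were seen per library and 54.0% (6073 of 11244) in all 3. Neither the bar set for a low share in each library nor that for a high share in all 3 was met. Genes at 0 in every library were left out, so the share that stayed at 0 was not measured and this test cannot decide. The median transcript length minus effective length was 10.1, 13.9 and 115 bases in MDSC2, PMN2 and MONO2, against 223 to 446 bases elsewhere. Y-linked genes held 202, 169 and 183 CPM in MDSC2, PMN2 and MONO2. They held 34.8 to 48.4 CPM in number 1 and 3.52 to 7.08 CPM in numbers 3 and 4. Neither value was used to test a source, and the sex of the mice behind each number was not tested. No biological explanation was tested, and the labels give no batch.

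T and NK cell markers were higher in PMN than in MDSC of the same number in 43 of 60 pairs of gene and number (71.7%), 20, 8 and 15 of 20 in numbers 1, 2 and 3. Monocytes carried over into PMN would bring monocyte transcripts too. These were higher in PMN in 33.3% of pairs (13 of 39), 8, 3 and 2 of 13 in numbers 1, 2 and 3, so this count leaves number 1 open. The excess of PMN1 over MDSC1 had a median of 26.7% of the MONO1 level over the T and NK cell markers (quartiles 13.3% and 43.6%). Over the monocyte genes it was 0.729% (quartiles -0.753% and 2.33%), with Ly6c1 and Ly6c2 above this at 101% and 39.0%. In number 3 the medians were 2.97% (quartiles 0.446% and 4.74%) and -0.424% (quartiles -0.766% and -0.276%). Cells carried over in the proportions of the MONO libraries would bring both lists in the same share, so these values argue against them as the source in numbers 1 and 3. T and NK cells in the PMN libraries cannot be told apart from expression by the PMN themselves, since the 71.7% restates the difference and would be the same under either, and the explanation is left open. Trac, the T cell receptor alpha constant gene, held 6.00, 0.557 and 1.78 CPM in PMN1, PMN2 and PMN3, against 0.317, 0.455 and 0.408 CPM in MDSC1, MDSC2 and MDSC3. For Cd3e the values were 5.73, 1.32 and 3.25 CPM against 0.740, 1.64 and 0.102 CPM. The surface markers that define PMN would exclude T and NK cells from a pure sort, but the purity of the libraries was not tested.

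Secondary granule genes differed among the PMN libraries, with PMN1 highest. The list mean was higher in PMN than in MDSC in 3 of 3 numbers (by 2.09, 1.42 and 0.15 on the log2 scale). A swap of the 2 labels within a number cannot be told apart from this, since the expected direction comes from the same libraries and the smallest gap lay below the SD of MDSC (0.892). Number 1 had the highest mean of this list in all 3 cell types, so a difference between the animals or days behind the numbers may be a source (3 of 3 cell types). In MONO its lead was small, with 6.16 log2 CPM in MONO1 against 6.02 in MONO3, so that cell type adds little. The labels do not say what the numbers stand for, and a difference in neutrophil maturity was not tested.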

How the results depend on the processing

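The fits without the libraries numbered 2 and the blocked list tests with an estimated correlation were chosen after the data were seen. MDSC against PMN gave 1 gene with the stricter filter, which tested 9384 genes, and 31 with DESeq2, against 0, and 0 without each library in turn. Genes higher in MDSC than in both others numbered 1 and 20 under the same alternatives, and genes lower than in both numbered 10 with DESeq2. MDSC against MONO gave 8414 genes with the replicate block, 8415 with the block on numbers 1 to 3, 7475 without the libraries numbered 2 and 7300 with both, against 3810, and 2544 to 5621 without each library in turn. PMN against MONO gave 6757, 6764, 4622 and 5422 genes under the same 4 alternatives, 3482 with the stricter filter and 3766 with DESeq2, against 2074, and 995 to 3367 without each library in turn. With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons, also with the block. Fry, which tests against no change and not against other genes, called 0 in MDSC against PMN and 6 in PMN against MONO. It was run only without the block. In MDSC against PMN the direction of 6 lists that were called in the main or the reduced fit turned when 1 library was left out. Their adjusted p then ranged from 0.000395 to 0.569 for primary granule genes (turned without PMN1, 0.0142), from 1.28e-08 to 0.749 for secondary granule genes (without PMN1, 0.749), from 5.38e-13 to 0.749 for G2 and M phase genes (without PMN1, 0.749), from 0.00838 to 0.787 for NADPH oxidase genes (without PMN2, 0.0458), from 2.32e-07 to 0.392 for glycolysis genes (without PMN2, 0.317) and from 4.54e-08 to 0.532 for respiratory chain genes (without MDSC2, 0.0362, and without PMN3, 0.0341). These unblocked fits left the same-numbered library of the other group without its partner, and the cause was not tested. Lists called in neither fit were not counted among the 6. Over all comparisons and alternatives, 100 list results changed direction with no call in either fit. Of 163 calls of named genes the replicate block kept all and of 45 list calls it kept 41, and the 4 lost are printed beside their results. It added 2 list calls and, among genes named with values, those of Ly6c1 and Ly6c2, and changed no other call of a named gene or a list printed here. DESeq2 gave an adjusted p for 157 of the 163 and kept the call of each. In simulated MDSC against PMN, fitted without the block, 14% of 4-fold changes were recovered with the spread of the unblocked fit and 93% with that of the blocked fit. The blocked fit itself was not simulated, so the 93% is not its rate of recovery. Both fits called 0 genes in the real libraries, which does not show that 4-fold changes were absent.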

Other observations

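The test of the sign of the deposited fold changes was chosen after the result was seen, and the tests of other splits before. Several lists not described above were called in no comparison or in 1. In cholesterol and lipid handling genes the median log2 fold change was -0.12 in MDSC against PMN (adjusted p = 0.91), 0.18 in MDSC against MONO (0.58) and 0.14 in PMN against MONO (0.57), while single members were called. Olr1, a scavenger receptor gene for oxidised lipoprotein, averaged 189 ± 31.2 CPM against 28.2 ± 14.02 CPM in MONO (log2 fold change 2.74, SE 0.45, adjusted p = 0.0023). Osteoclast markers were not called as a list (-0.02, 0.24 and 0.21, adjusted p = 0.83, 0.92 and 0.98), but Atp6v0d2, a proton pump subunit gene of osteoclasts and macrophages, averaged 41.6 ± 11.6 CPM against 1.05 ± 0.908 CPM in MONO (log2 fold change 5.30, SE 0.67, adjusted p = 0.00085) and was also higher in PMN than in MONO (log2 fold change 5.32, SE 0.69, adjusted p = 0.0021).

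Eosinophil, basophil and mast cell markers had a median of -1.07 in MDSC against PMN (adjusted p = 0.61, called lower without PMN3 at 0.000606 and with no filter on low counts at 0.0482), 1.95 in MDSC against MONO (0.22) and 2.67 in PMN against MONO (camera adjusted p = 0.048, and adjusted p = 0.58 with an estimated correlation). The last call was lost with the replicate block (0.0756), without MDSC1 (0.0536) and without PMN1 (0.171). It was also lost with DESeq2 (0.061), limma-voom (0.126), DESeq2 size factors (0.061), upper-quartile factors (0.0835), only the 2 groups compared (0.119) and genes on several lists left out (0.0568). Against no change, which camera does not test, fry gave adjusted p = 0.103. Siglecf, a lectin gene of eosinophils, averaged 26.8 ± 10.6 CPM against 1.75 ± 0.865 CPM in MONO (log2 fold change 3.94, SE 0.60, adjusted p = 0.0017). Erythroid markers (-0.66, 1.37 and 2.12, adjusted p = 0.74, 0.53 and 0.57) and megakaryocyte and platelet markers (-0.37, 1.70 and 2.02, adjusted p = 0.74, 0.21 and 0.13) were not called. Bone, stromal, endothelial and muscle markers were not called (-0.06, 1.65 and 1.31, adjusted p = 0.27, 0.2 and 0.23). In MDSC against PMN they were called higher with the replicate block (0.0482), without the libraries numbered 2 (0.0274), MDSC3 (0.0203), MDSC4 (0.0218) or PMN2 (0.00313), although their median there was below 0. The call with the block was lost with the block and an estimated correlation (adjusted p = 0.76). Hematopoietic progenitor markers were not called either (-0.63, -0.37 and 0.18, adjusted p = 0.16, 0.22 and 0.47), and were called lower in MDSC than in PMN without MDSC2 (0.0343) or PMN3 (0.00483), and lower in MDSC than in MONO with no filter on low counts (0.0405). B cell and plasma cell markers had medians of 0.48 in MDSC against MONO (adjusted p = 0.72) and 1.36 in PMN against MONO (0.15), the latter called higher without the libraries numbered 2 (0.0448), MONO2 (0.0299) or PMN3 (0.0252). In MDSC against PMN, camera placed the lipid, erythroid, osteoclast and bone lists higher in MDSC although their medians were below 0, and in PMN against MONO the progenitor list lower although its median was above 0.

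In the authors' deposited tables used here, 22, 5259 and 2895 genes were past an adjusted p of 0.05 in MDSC against PMN, MDSC against MONO and PMN against MONO. Of the genes called by edgeR, 3717 of 3810 and 1958 of 2074 were also past it in the last 2 comparisons. Among the genes past that threshold and tested by edgeR, the deposited log2 fold changes had the opposite sign of the edgeR ones in 100% (8119 of 8119). This is what a coding with the groups in the reverse order of the table name gives. Directions given here come from the counts.

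In MDSC against PMN the real split gave 0 genes, so all 35 splits of the 7 libraries had to give as many, and their count tests nothing. The highest other gave 1030, with MDSC1, MDSC3, MDSC4 and PMN3 against the rest, which points to a structure of the samples. In MDSC against MONO only the real split, 1 of 35, gave 3810 genes, and the highest other gave 524. That share lay under 0.05, but over splits that ignore the numbers, so it does not exclude chance. Of the 8 that part all 3 pairs of numbers the real one alone gave as many, and 8 are too few for a share under 0.05. In PMN against MONO the 10 splits are too few for a share under 0.05, with 2074 genes in the real split and 0 in the highest other, as 1 of 10. For lists, 16 of 35 splits in MDSC against PMN gave as many as the real 14 (highest other 18) and 19 of 35 in MDSC against MONO gave as many as the real 15 (highest other 20), so chance could not be excluded for the number of lists. In PMN against MONO 3 of 10 gave as many as the real 16 (highest other 17), again with too few splits. Among the splits that part all 3 pairs of numbers, as the real one does, the highest other count of genes was 0 in each comparison.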
